A study of Phaeodactylum tricornutum with 56 samples.

How the data were processed

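RNA of Phaeodactylum tricornutum cultures was measured on 56 two-colour Agilent arrays, 8 on each of 7 slides scanned on 2 days. There were 5 arrays for each of 10 stressors and 6 for control cultures. Per the labels, cultures grew for 96 h, cells were broken with glass beads, and RNA was extracted with TRIzol and cleaned on columns. Each array carried 15208 spots of 4749 probes, with 3 spots for 3788 probes and 4 for 961, and 536 control spots.

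The authors scanned the arrays and extracted the signals with Feature Extraction 10.7.3.1. Per the file headers, the array files hold the intensity of each spot in both channels as median signals, backgrounds and processed signals. The deposited array files also hold a log10 ratio of red over green. The deposited value table of the series is in log2, green over red, and correlated with the log10 ratio at r between -1.00 and -0.75 over probes on each array. The medians of its columns ran from -0.26 to 0.04.

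Median signals were used, since the files hold no foreground means, which the plan made before the data were examined had named. They were background corrected with normexp (offset 50) and normalized within arrays by loess with control spots left out of the curve. Spots that the extraction software had marked as non-uniform were left out, at most 7 on an array. The log2 ratios of exposed (green) over reference (red) RNA were averaged over the spots of a probe. Probes were kept if well above background on at least 5 arrays in at least 1 channel, which left 4485.

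One limma fit (limma 3.58.1, R 4.3.3, data.table in version 1.17.8) over the 56 arrays with a mean per group gave every comparison, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Stressors were compared with control, related stressors with each other, and the mixture with the sum of ammonia, cadmium and salinity. The median standard error of a log2 difference was 0.09 against control, 0.10 between stressors and 0.19 for the departure from the sum. Each SE came from a spread per probe pooled over all groups, so it does not measure the spread of the groups compared. Figures were drawn with matplotlib 3.10.9. The probes to name were those past the threshold whose ratios lay on 1 side of the mean of the other group on every array, taken by size. As the files pair no gene names with the probes, at most 2 rises and 2 falls are named per comparison, as fixed before the data were examined. Of the 4749 probes, 99 keep a whole protein accession, of GenBank, while the reference table of 10398 genes holds RefSeq accessions, so 0 could be matched. This does not say that the genes are missing from it. The 33 gene lists fixed in advance and the check of direction by nitrate reductase could therefore not be run.

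Where a probe was not well above background on any array of 1 group, its change is given as a lower bound from the green channel after loess and quantile normalization between arrays. The bound puts the lowest well-above-background signal of an array in place of any weaker signal. For CUST_2956_PI426266160 no signal was weaker, so its folds are measured differences in green and not bounds. All these values are open to dye bias, and none is given where the channel alone exceeded the ratio. Correlations and covariances between comparisons with control share the control arrays. They were set against 500 simulations of unchanged groups and recomputed with the controls split 3 and 3. The simulated controls were drawn from the deviations of arrays of all groups, so their limits need not be those of the 6 control arrays. Overlaps of calls were set against independent lists. Each probe has 1 spread in all comparisons, so an overlap above independent lists does not by itself show a like response. The channel that carried the exposed RNA was tested by fitting each channel alone. To see whether differences held within slides, probes were called without the arrays of a slide and their sign was read on that slide, a test chosen after seeing the data. For unchanged probes about as many would match as not, but probes of an array do not vary independently.

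The limma fit was tested on simulated data with 200 of 4485 probes changed in the copper comparison, over 20 runs. The changes were added after normalization, so background correction, loess and the filter were not tested. Every real comparison with control called more than 200 probes. The fit recovered 79.6% of changes of 0.5 and 96.5% of changes of 1 on the log2 scale, with no change called in the wrong direction. The median number of false calls was 3.5 and the highest 182, and 3 runs had more than 10.

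The alternatives fixed before the data were examined were no background correction, the processed signals, median centring in place of loess, quantile normalization of the average signal after loess, the deposited value table, no filter and a strict filter on dim probes, slide and replicate number as blocks, eBayes with a trend and robust fitting, a fit of only the groups compared, ratios tested against 0 without the control arrays, and leaving out each array. Green signal as a covariate, scan day as a block and leaving out the 3 arrays with under 65% of probes well above background in green were added after seeing the data.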

Results

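The data are 56 two-colour oligonucleotide arrays of RNA from Phaeodactylum tricornutum, a marine diatom whose genome is sequenced and which serves as a test organism for pollutants. Cultures were grown for 96 h in seawater with added nutrients and 1 of 10 stressors, with 5 arrays per stressor and 6 arrays of control cultures. The stressors were copper sulphate at 2 µg/L, cadmium sulphate at 5 µg/L, silver nitrate at 35 µg/L, the herbicide simazine at 75 µg/L, ammonium sulphate at 260 µM, seawater of 15 ppt salinity, a mixture of ammonium sulphate, cadmium sulphate at 35 µg/L and 10 ppt salinity, the water-accommodated fraction of crude oil at 5 g/L, an oil dispersant at 25 mg/L, and crude oil at 0.1 g/L treated with 10 mg of dispersant. Control cultures and those of the other 8 stressors had 260 µM nitrate, while in the ammonia and mixture cultures ammonium sulphate took the place of nitrate. Salinity replicate 4 is given as 15 ppt in its title and as 10 ppt in its treatment label. Every array carried the RNA of its culture and a control RNA as reference, per the channel labels that of control replicate 2 throughout. The series text speaks of 6 split controls, so which control RNA served as reference on each array is not settled. If the channel labels hold, the array of control replicate 2 carries that RNA in both channels. The SD of its log2 ratios over probes was 0.09 against a median of 0.14 on the other control arrays, and it is among the 6 control arrays. Without it no count against control moved by over 1.5 times. The question is which transcripts each stressor raised or lowered against the unexposed cultures, and whether related stressors did so alike.

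The arrays held 4749 probes, of which 4485 were bright enough to test. The files do not pair the probes with gene names, so probes are given by their identifiers and no pathway is described. The share of probes well above background in the channel of the exposed RNA ran from 41.7% on oil replicate 3 to 93.9%, and in the reference channel from 84.9% to 95.9%. No probe was saturated. The number of arrays limits the precision, and the median standard error of a log2 difference between a stressor and the control was 0.09. Arrays of the same group correlated with a median r of 0.79 over probes, those of different groups with 0.13.

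The labels disagree on the dyes: the channel labels give the exposed RNA as Cy3 (green) and the reference as Cy5 (red), while the labelling protocol gives the reference as Cy3. Tested channel by channel, 4373 probes differed between the groups in green and 29 in red, and red deviated less than green from the mean of the other arrays on all 56 arrays. The median SD of a probe over the arrays was 0.31 in green and 0.10 in red (log2). The exposed RNA was therefore taken as green, and each direction below is likely rather than settled. Turned the other way, every rise below would be a fall of the same size and every fall a rise. Of the 1540 pairs of arrays, 31 correlated below -0.3, the lowest being copper replicate 4 with control replicate 1 at r = -0.44.

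The median brightness of the exposed channel differed between groups. The log2 median green signal was 7.91 ± 0.62 (SD, n = 5) on the copper arrays, 7.64 ± 0.92 (n = 5) with salinity and 6.17 ± 0.36 (n = 6) in control, and it was lowest with the mixture, at 5.46 ± 0.45 (n = 5). The first component of the differences between arrays of a group held 33.1% of their variance and correlated with the green signal at r = 0.83. The red signal was 7.79 ± 0.62 (n = 5) with copper and 7.91 ± 0.34 (n = 6) in control.

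**Figure D1:**
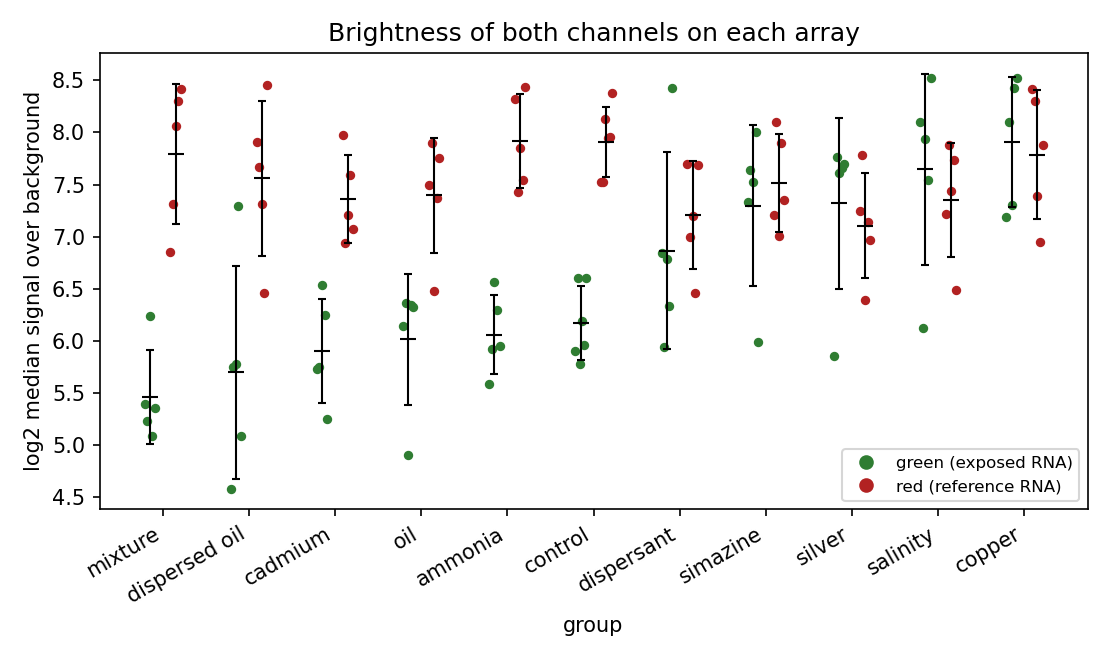
Log2 median signal over background of the green and red channel on each of the 56 arrays, by group, with the mean and SD of each group. Green ran from a mean of 5.46 on the mixture arrays to 7.91 on the copper arrays.

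The ammonia cultures, which had ammonium in place of nitrate, differed from control over most of the array. The presence of ammonium and the absence of nitrate cannot be separated in this comparison. Of 4485 probes, 1638 rose and 1652 fell against control, 73.4% in all, and 623 rises and 389 falls were at least 2-fold. The largest fall was in CUST_2349_PI426266160, whose log2 ratio was -8.95 ± 0.47 (SD, n = 5) with ammonia and -0.18 ± 0.04 (n = 6) in control, a log2 difference of -8.78 (limma, adjusted p = 5.15e-21). CUST_732_PI426266160 fell by 6.97 on the log2 scale (SE 0.63). The largest rises were in CUST_3841_PI426266160, by 6.02 ± 0.33 (SE; replicate 4 lay apart at a log2 ratio of 3.45), and CUST_2411_PI426266160, by 5.76 ± 0.17 (SE). A slide block gave 3254 called probes, and of the probes called without the arrays of a slide, 94.4% to 97.7% had the same sign on that slide, over the slides that held both groups. With median centring in place of loess, 821 rose and 1757 fell, and the median of all probes lay at -0.20, so the even split of rises and falls depends on the loess step. So does its rank as the stressor with the most calls, since median centring called 2578 probes with ammonia and 2781 with salinity. The mixture ranked above ammonia in a fit of only the groups compared (3393 and 3133) and with the deposited value table (3390 and 3389). The processed signals gave a median of -0.20.

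The mixture, which held ammonium in place of nitrate, a higher dose of cadmium than the cadmium cultures and low salinity, gave 1557 rises and 1592 falls, 522 and 336 of them at least 2-fold. CUST_2349_PI426266160 and CUST_732_PI426266160 were again the largest falls, with log2 differences of -8.08 and -6.65. CUST_3841_PI426266160 rose by 6.45 ± 0.33 (SE). CUST_4693_PI426266160 was not well above background on any control array and was at least 34.3-fold higher with the mixture (adjusted p = 7.77e-39). In a fit with slide as a block 2986 probes were called, and on slides left out of the calls 98.6% to 98.8% had the same sign. Median centring gave 666 rises and 1591 falls and a median of all probes of -0.14, and the processed signals a median of -0.22.

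Whether the mixture acted like its components was asked directly. The log2 fold changes of the mixture and ammonia correlated at r = 0.93 over probes, against 0.11 for cadmium and 0.13 for salinity with the mixture. Ammonia and the mixture are also the only groups without nitrate. Probes are not independent replicates, and all comparisons with control share the control arrays. Unchanged groups simulated against shared controls gave a mean r of 0.45 and a mean covariance of 0.009, with 95% of the covariances between -0.002 and 0.026. The covariance with the mixture was 0.98 for ammonia, 0.039 for cadmium and 0.054 for salinity. Cadmium and the mixture shared 385 falls (247 for independent lists) and salinity and the mixture 479 (316). Their shared rises lay near independent lists, at 226 (223) and 350 (347). With the controls split 3 and 3 the mean r of ammonia and the mixture was 0.93. Both comparisons called 1338 probes up and 1378 down, where independent lists would share 569 and 586, and 47 went opposite ways. A direct test found 1493 probes that differed between the mixture and ammonia, 638 higher and 855 lower with the mixture, and 96 by at least 2-fold. In 74.4% of these the mixture lay nearer to the control than ammonia did. The log2 ratios of the spike-in control spots also spread less with the mixture (mean SD 1.12) than with ammonia (1.33). A compression of ratios on the mixture arrays is therefore not excluded. Median centring called 542 probes, and a fit of these groups alone 460 (227 higher and 233 lower). The strict filter turned the split to 291 higher and 238 lower. The r of salinity and the mixture turned to -0.21 with median centring.

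The probes that lay highest over ammonia in the mixture were also raised by low salinity. CUST_4693_PI426266160 was higher with the mixture than with ammonia by 5.87 ± 0.13 on the log2 scale (SE) and CUST_1840_PI426266160 by 4.59 ± 0.24 (SE), and both rose with salinity alone. On the ammonia arrays these probes were well above background on 2 and 3 of 5 arrays. The SE pools the spread of all groups. The log2 ratios of CUST_4693_PI426266160 had an SD of 0.47 with the mixture and 0.33 with ammonia (n = 5 each). CUST_3090_PI426266160 was lower with the mixture by 2.90 on the log2 scale. CUST_2956_PI426266160, not well above background on any mixture array, was 7.10-fold higher with ammonia in the green channel. A slide block gave 1432 probes that differed, and on slides left out of the calls 74.5% to 81.9% had the same sign. The mixture differed from cadmium at 2991 probes (1492 higher and 1499 lower, 2895 with slide as a block) and from salinity at 3171 (1608 and 1563, 2998 with slide as a block). Median centring turned the split against cadmium to 789 higher and 1260 lower. With the processed signals the median of all probes was -0.19 against cadmium and -0.24 against salinity. Against salinity they gave 1445 higher and 1966 lower, and median centring 1589 and 1875. Against cadmium 96.8% to 99.3% had the same sign on slides left out. No slide held both mixture and salinity arrays.

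Against cadmium, the mixture was at least 35.8-fold higher in CUST_4693_PI426266160 and lower in CUST_630_PI426266160 by a log2 difference of -6.40 ± 0.22 (SE), a probe that cadmium alone raised. Against salinity, the mixture was higher in CUST_1842_PI426266160 by 5.30 ± 0.19 (SE) and lower in CUST_2349_PI426266160 by a log2 difference of -7.24 ± 0.53 (SE).

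The mixture was also set against the sum of the changes under ammonia, cadmium and salinity, at the doses the labels give, which are not those in the mixture for cadmium and salinity. The departure from the sum passed the threshold at 1593 probes, 746 above and 847 below the sum (1476 with slide as a block). The slope of the mixture on the sum was 0.64 over probes (r = 0.85), and on ammonia alone 0.84 (r = 0.93). The mean SD of the spike-in log2 ratios was 1.12 with the mixture, 1.33 with ammonia, 1.11 with cadmium and 1.43 with salinity. Compressed ratios on the mixture arrays are therefore not excluded as a part of the slope on the sum. The mixture arrays are the same in both slopes, so their compression does not by itself account for the step from 0.84 to 0.64. CUST_2161_PI426266160, which rose with cadmium alone, lay below the sum (adjusted p = 9.08e-22), but it was not well above background on any mixture array, so the size of its departure is not given. CUST_2625_PI426266160 lay above the sum by 5.25 ± 0.68 (SE). Median centring gave 810 above and 350 below the sum, with a median of all probes of 0.14.

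Cadmium raised 642 probes and lowered 696, of which 118 changed at least 2-fold. CUST_2161_PI426266160 rose to a log2 ratio of 4.89 ± 0.52 (SD, n = 5) against -0.03 ± 0.10 (n = 6) in control, where it was well above background on 1 array (adjusted p = 3.13e-36). CUST_630_PI426266160 rose by 4.57 ± 0.21 (SE). CUST_343_PI426266160 fell by 2.59 (replicate 5 lay apart at a log2 ratio of -1.28) and CUST_2202_PI426266160 by 2.10 on the log2 scale. With slide as a block 1359 probes were called, and on slides left out of the calls 98.8% to 99.6% had the same sign. Median centring left 88 rises and 241 falls, with a median of all probes of -0.12.

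Copper raised 898 probes and lowered 768, but only 4 rises and 44 falls reached 2-fold. CUST_4091_PI426266160 had a log2 ratio of 1.17 ± 0.35 (SD, n = 5) against -0.16 ± 0.08 (n = 6) in control (adjusted p = 4.36e-05), and CUST_2764_PI426266160 rose by 1.12 ± 0.34 (SE). CUST_3139_PI426266160 fell by 3.13 on the log2 scale (SE 0.33, adjusted p = 1.43e-09). CUST_1866_PI426266160 fell by 3.16 (SE 0.93), yet its controls spread by 0.71 (SD, n = 6), and with the green signal of each array as a covariate, a choice made after seeing the data, its log2 difference was -0.23 (adjusted p = 0.848). In that fit CUST_2764_PI426266160 differed by 0.99 with adjusted p = 0.0569. Fitted with slide as a block, 1646 probes were called, and on slides left out 90.6% to 99.1% had the same sign. With the green signal as a covariate 1197 probes were called, 897 of them among the 1666. The processed signals called 986. Median centring gave 1012 rises and 1444 falls.

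Silver raised 572 probes and lowered 446, with 4 and 46 at least 2-fold. CUST_2956_PI426266160 rose by 1.20 ± 0.28 (SE, adjusted p = 0.0016) and CUST_2994_PI426266160 by 1.14 ± 0.31 (SE). CUST_4091_PI426266160, which copper raised, fell by 2.23 (SE 0.25), and CUST_343_PI426266160, which cadmium lowered, fell by 2.15 (SE 0.37) on the log2 scale. In a fit with slide as a block 1078 probes were called, and on slides left out 97.7% to 100% had the same sign. With the green signal as a covariate 723 probes were called, 594 of them among the 1018. The count and its split moved with the normalization: the processed signals gave 262 rises and 356 falls, the deposited log2 ratios 248 and 356, and median centring 986 and 1379.

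The 3 metals were compared with each other. The log2 fold changes of copper and silver correlated at r = 0.23, of copper and cadmium at 0.06 and of cadmium and silver at -0.13. Copper and cadmium ran from -0.02 without cadmium replicate 3 to 0.13 without cadmium replicate 5 (0.02 without copper replicate 2 or cadmium replicate 4, 0.11 without copper replicate 5 and 0.12 without cadmium replicate 1), so no sign is given to their correlation. Cadmium and silver lay at -0.08 without silver replicate 5 and at -0.19 without silver replicate 1. These values depend on the normalization also: with median centring r was 0.75, -0.09 and -0.19, and with the green signal as a covariate -0.00, 0.30 and 0.04. The covariances were 0.024, 0.008 and -0.014, where 95% of simulated unchanged groups lay between -0.002 and 0.026. The simulated controls came from arrays of all groups, so these limits need not be those of the real controls. With split controls the covariances were 0.022, 0.007 and -0.016, and the mean r was 0.22, 0.05 and -0.13. All 3 metals raised 45 probes and lowered 74, where independent lists would share 16.4 and 11.9. All comparisons share the spread of each probe, so counts above independent lists do not by themselves show a like response. Copper and silver called 199 probes up together (115 for independent lists) and 158 down (76.4), with 131 opposite. Copper and cadmium called 202 up together (129) and 241 down (119), and cadmium and silver 74 (81.9) and 114 (69.2). Tested directly, silver and copper differed at 1662 probes, silver and cadmium at 2133, and cadmium and copper at 2029, with 1530, 2139 and 1918 called with slide as a block. On slides left out of the calls 86.7% to 99.2% had the same sign for silver and copper, 98.6% for silver and cadmium on 1 slide, and 99.1% for cadmium and copper on 1 slide.

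The probes below were picked for the largest differences between the metals, which favours opposite movement, and the doses differed. Over all probes, opposite calls numbered 145 for copper and cadmium (249 for independent lists). They numbered 131 for copper and silver (187) and 166 for cadmium and silver (153). CUST_3139_PI426266160 rose to 4.09 ± 0.49 (SD, n = 5) with cadmium and fell to -3.16 ± 0.37 (n = 5) with copper, a log2 difference of 7.25 (adjusted p = 4.34e-23), and the log2 difference of silver from cadmium in it was -5.29 (SE 0.34). CUST_630_PI426266160 was 6.03 ± 0.22 (SE) higher on the log2 scale with cadmium than with copper, and silver lay below cadmium in it by 5.64 (SE 0.22). CUST_4091_PI426266160 was lower with silver than with copper by a log2 difference of -3.56 ± 0.26 (SE), and lower with cadmium than with copper by -2.83 ± 0.26 (SE), where it was well above background on 3 of 5 cadmium arrays. CUST_1250_PI426266160 was higher with silver than with copper by 2.57 ± 0.41 (SE). CUST_2956_PI426266160, not well above background on any cadmium array, was 5.59-fold higher with silver in the green channel. Between silver and copper the processed signals called 496 higher and 609 lower, and median centring called 820.

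**Figure D2:**
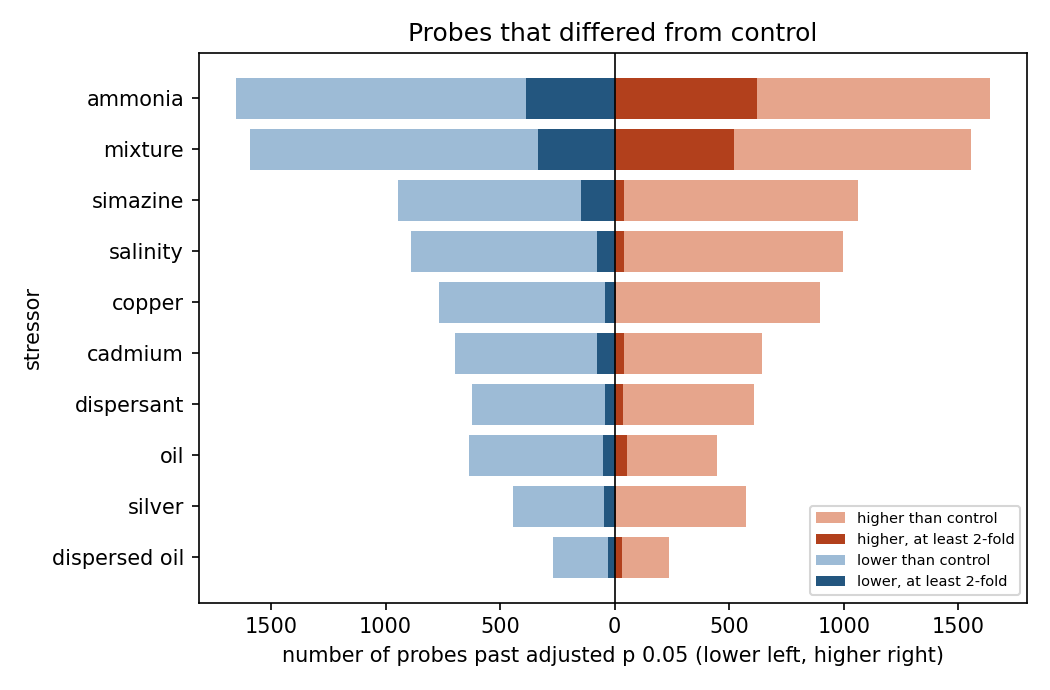
Number of probes higher (right) and lower (left) than control under each stressor at adjusted p under 0.05, with those that changed at least 2-fold in the darker colour. Ammonia called 3290 probes and the mixture 3149.

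Simazine, a herbicide that blocks electron transport at photosystem II, raised 1064 probes and lowered 946, and more falls (149) than rises (40) reached 2-fold. CUST_3904_PI426266160 had a log2 ratio of -3.37 ± 0.44 (SD, n = 5) against 0.08 ± 0.07 (n = 6) in control (adjusted p = 1.44e-11), and CUST_3769_PI426266160 fell by 2.97 (SE 0.25). CUST_2204_PI426266160 rose by 3.00 ± 0.19 (SE) and CUST_3825_PI426266160 by 2.46 ± 0.14 (SE). With slide as a block 1699 probes were called, and on slides left out 96.4% to 99.1% had the same sign. Median centring gave 802 rises and 1372 falls.

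Low salinity raised 999 probes and lowered 890, with 41 and 79 at least 2-fold. CUST_4693_PI426266160 had a log2 ratio of 3.69 ± 0.34 (SD, n = 5) and was at least 9.67-fold higher than in control, where it was not well above background on any array (adjusted p = 4.54e-29). CUST_1840_PI426266160, also not well above background in control, rose as well (adjusted p = 1.53e-16), with replicate 5 apart at a log2 ratio of 2.84. The size of its rise is not given, as the green channel alone and the ratio do not give a common lower bound. CUST_3177_PI426266160 fell by 2.62 (SE 0.14) on the log2 scale. CUST_1866_PI426266160 fell as well, but with the green signal as a covariate its log2 difference was -1.02 (adjusted p = 0.26). A slide block gave 1770 called probes. With the green signal as a covariate 1620 were called, 1303 of them among the 1889. On slides left out 80.7% to 99.5% had the same sign. Median centring gave 1240 rises and 1541 falls and the strict filter 319 and 409, so which direction prevailed depends on these choices.

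Crude oil raised 448 probes and lowered 638, with 54 and 51 at least 2-fold. CUST_2673_PI426266160 rose to a log2 ratio of 4.92 ± 0.65 (SD, n = 5) against -0.13 ± 0.09 (n = 6) in control, where it was well above background on 3 arrays (adjusted p = 1.43e-19), and CUST_2172_PI426266160 rose by 4.46 ± 0.34 (SE). CUST_831_PI426266160 and CUST_1587_PI426266160 fell, with log2 differences of -3.51 (SE 0.36) and -2.94 (SE 0.35). Fitted with slide as a block, 1243 probes were called, and on slides left out 98.4% to 99.4% had the same sign. Median centring left 67 rises and 248 falls and a median of all probes of -0.13.

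The dispersant raised 608 probes and lowered 624, with 37 and 40 at least 2-fold. CUST_2172_PI426266160 rose by 3.51 ± 0.34 (SE; replicate 5 lay apart at a log2 ratio of 2.62) and CUST_231_PI426266160 by 2.42 ± 0.27 (SE). CUST_1587_PI426266160 fell by 3.78 (SE 0.35) and CUST_2763_PI426266160 by 3.58 (SE 0.40). With slide as a block 1230 probes were called, and on slides left out 99.0% to 99.4% had the same sign. Median centring gave 467 rises and 1268 falls.

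Dispersed oil raised 238 probes and lowered 270, with 30 and 28 at least 2-fold. The log2 ratios of the spike-in control spots spread least of all groups with dispersed oil (mean SD 0.89). Their mean SD was 1.14 with oil, 1.30 with dispersant and 1.28 in control. A compression of ratios on the dispersed oil arrays is therefore not excluded as a part of the low count. CUST_2172_PI426266160 rose by 3.42 ± 0.34 (SE, adjusted p = 1.21e-09), and CUST_831_PI426266160 and CUST_1587_PI426266160 fell, with log2 differences of -2.84 (SE 0.36) and -2.70 (SE 0.35). On the dispersed oil arrays the log2 ratios of these probes had SDs of 1.28, 1.43 and 1.54 in that order (n = 5). The SEs and the adjusted p pool the spread of all groups and do not measure this spread. CUST_1677_PI426266160 passed the test at 2.41 ± 0.74 (SE), a size that rested on replicate 5 at a log2 ratio of 9.65. Without replicate 5 the log2 difference was 0.58 (adjusted p = 0.036), and without the 3 dim arrays 0.38 (adjusted p = 0.239). On replicate 5 the loess step moved 276 probes by more than 2 on the log2 scale against median centring, and it did so on 5 arrays in all. Without oil replicate 3 and dispersed oil replicates 1 and 5, a choice made after seeing the data, 837 probes were called. Leaving out replicate 5 alone gave 787, replicate 2 alone 283 and replicate 3 alone 281. The processed signals called 1327 probes, the deposited log2 ratios 485 rises and 836 falls, and median centring 16 rises and 84 falls with a median of all probes of -0.11. With slide as a block 515 were called, and on slides left out 97.2% to 100% had the same sign.

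Oil, dispersant and dispersed oil were compared as a family. In common they raised 165 probes and lowered 215, where independent lists would share 3.22 and 5.34. The log2 fold changes correlated over probes at r = 0.87 for oil and dispersed oil, 0.82 for dispersant and dispersed oil and 0.74 for oil and dispersant. In simulated unchanged groups the mean was 0.45 and 95% lay between -0.14 and 0.82. The r of oil and dispersant lay within that range, and that of dispersant and dispersed oil at its upper limit. The simulated controls were drawn from arrays of all groups, so the range does not show what the 6 control arrays alone can give. With split controls the mean r was 0.84, 0.79 and 0.72. The covariances were 0.089, 0.079 and 0.093, above the upper limit of 0.026 in the simulation, and 0.087, 0.077 and 0.091 with split controls. With median centring r was 0.82, 0.49 and 0.47. Oil and dispersed oil called 193 probes up and 253 down together (23.8 and 38.4 for independent lists), and none opposite. Dispersant and dispersed oil shared 186 and 228 (32.3 and 37.6), and oil and dispersant 269 and 386 (60.7 and 88.8).

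These 3 were tested against each other. Compressed ratios on the dispersed oil arrays are not excluded as a part of their differences from oil and from dispersant. Dispersed oil and oil differed at 7 probes, 1 higher and 6 lower with dispersed oil (325 at an unadjusted p under 0.05). CUST_2673_PI426266160 was lower with dispersed oil than with oil by a log2 difference of -3.87 ± 0.29 (SE, adjusted p = 3.74e-14), and CUST_255_PI426266160 by -2.60 ± 0.33 (SE). The 1 probe higher with dispersed oil, CUST_3247_PI426266160, differed by 0.81 ± 0.16 (SE). The oil doses were 5 and 0.1 g/L. A slide block gave 15 probes that differed, 7 higher and 8 lower, and the green signal as a covariate 6 higher and 12 lower. Of 8 probes called without a slide 6 and 7 had the same sign on it. Leaving out dispersed oil replicate 2 or oil replicate 3 gave 12 probes each and leaving out oil replicate 5 gave 11. Median centring left 0 higher and 4 lower, and a fit of these groups alone 2 lower. The processed signals called 14.

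Oil and dispersant differed at 253 probes, 80 higher and 173 lower with oil (959 at an unadjusted p under 0.05). CUST_2673_PI426266160 was 4.94 ± 0.29 (SE) higher on the log2 scale with oil, where dispersant lay at -0.02 ± 0.07 (SD, n = 5), and CUST_255_PI426266160 was 2.64 ± 0.33 (SE) higher. CUST_2144_PI426266160 was lower with oil by a log2 difference of -1.63 ± 0.28 (SE; dispersant replicate 5 lay apart at -0.61) and CUST_14_PI426266160 by -1.49 ± 0.26 (SE), with replicate 5 apart in both groups, at -1.48 and 0.14. A fit of these groups alone called 142. A slide block gave 206 probes that differed, and on slides 2, 5 and 7, left out of the calls, 90.9% to 100% had the same sign. On slide 3, with oil replicates 2 and 3 and dispersant replicate 5, 46.3% of 380 probes called without it had the same sign, so the difference did not hold there. Leaving out oil replicate 5 gave 129 and dispersant replicate 3 gave 109.

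Dispersed oil and dispersant differed at 78 probes, 28 higher and 50 lower with dispersed oil (742 at an unadjusted p under 0.05). CUST_2673_PI426266160 was higher by 1.07 ± 0.29 (SE, adjusted p = 0.0411) and CUST_4369_PI426266160 by 0.77 ± 0.13 (SE). CUST_2144_PI426266160 was lower by a log2 difference of -1.09 ± 0.28 (SE, adjusted p = 0.0349) and CUST_1702_PI426266160 by -0.80 ± 0.13 (SE). A slide block gave 7 probes that differed, and the calls of CUST_2673_PI426266160 (log2 difference 1.10, adjusted p = 0.0856) and CUST_2144_PI426266160 (-0.80, adjusted p = 0.197) were lost. On slides left out of the calls 17 of 23 and 10 of 16 probes had the same sign. The count rested on single arrays: it was 275 without dispersed oil replicate 4, 161 without dispersant replicate 5, 51 without dispersant replicate 4, 38 without dispersed oil replicate 5, 23 without dispersed oil replicate 3, 13 without dispersed oil replicate 1, 11 without dispersant replicate 1 and 8 without dispersant replicate 3. Median centring gave 12 higher and 46 lower, and the deposited log2 ratios 102 and 299. The split turned to 23 higher and 15 lower with the green signal as a covariate. Without dispersant replicate 5 it turned to 88 and 73. A fit of these groups alone called 3.

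**Figure D3:**
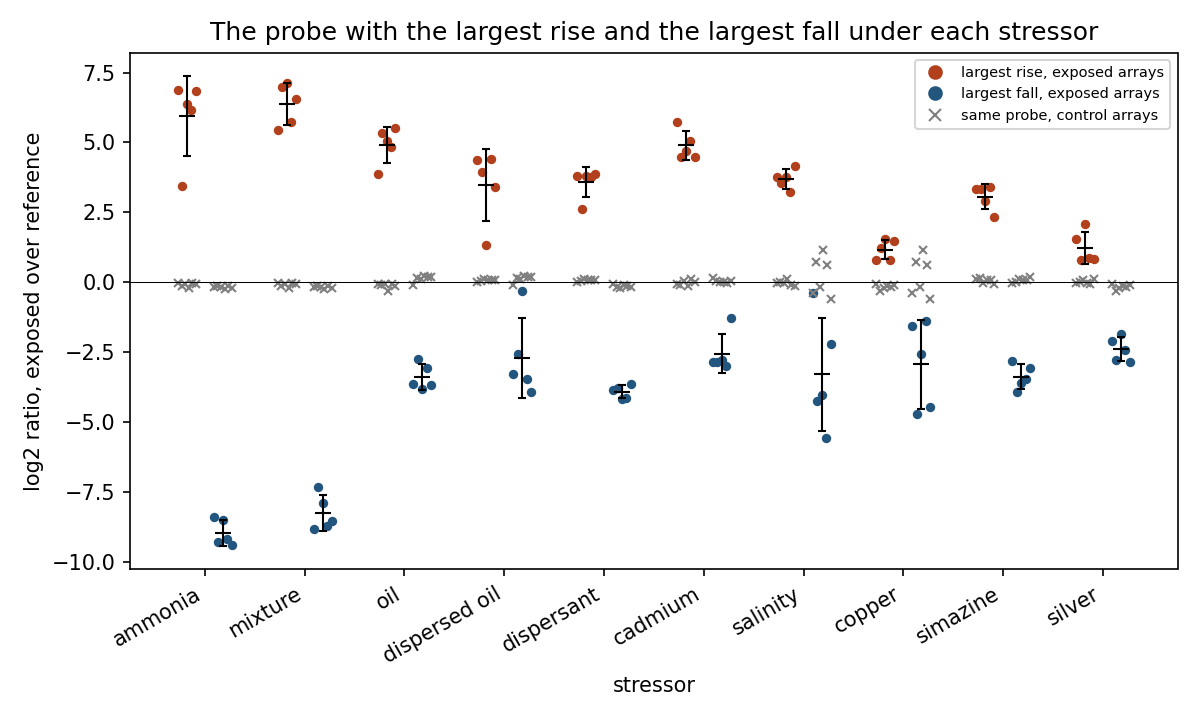
Log2 ratio of exposed over reference RNA on each array for the named probe with the largest fitted rise (red) and fall (blue) under each stressor, with mean and SD over 5 arrays, and the same probe on the 6 control arrays (grey crosses). The largest fall under ammonia had a mean of -8.95, and the copper and salinity probe that fell most had scattered controls.

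Outside these families the highest correlation was that of copper and salinity, at r = 0.64 over probes (mean 0.62 with split controls, covariance 0.0905 against 0.009 simulated). They raised 528 probes together and lowered 452, where independent lists would share 200 and 152, and 51 went opposite ways. The r was 0.64 with slide as a block, 0.57 with the green signal as a covariate and 0.86 with median centring. Silver and oil lay apart, at r = -0.28, with 207 probes opposite (126 for independent lists). Yet they shared 88 falls (63.4 for independent lists), while their shared rises numbered 28 (57.1). Their log2 median green signals were 7.32 and 6.02. This pair was not examined under the other settings, so a part of brightness in it is not excluded.

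**Figure D4:**
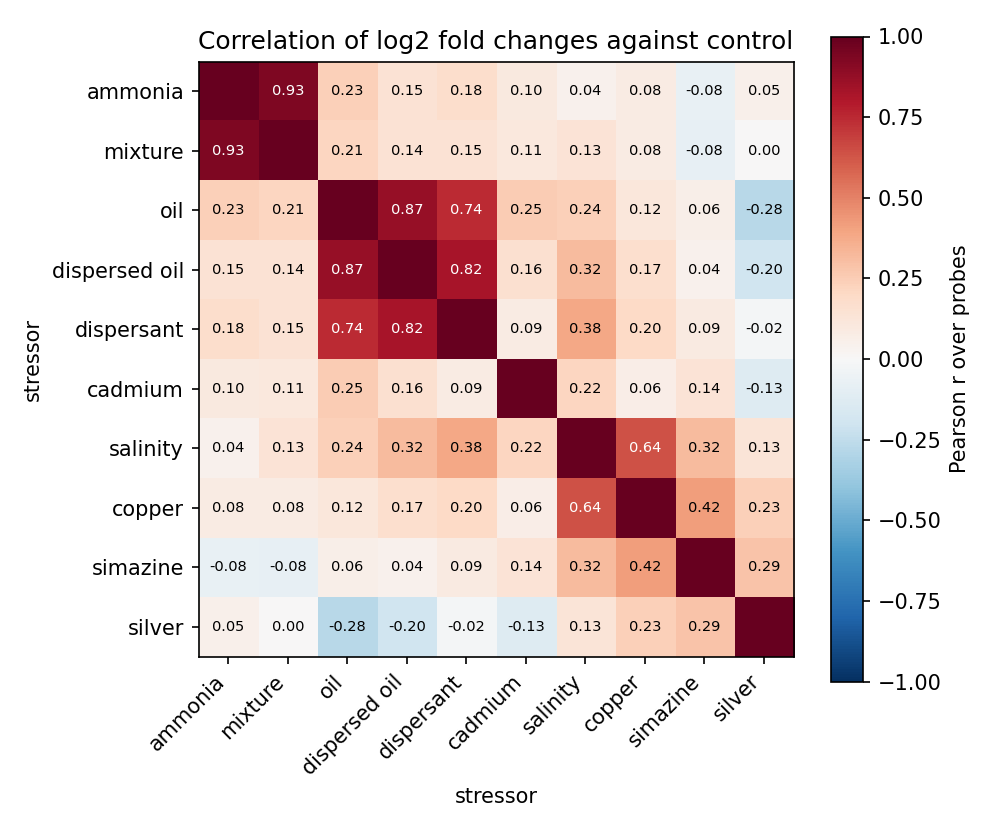
Pearson correlation over 4485 probes of the log2 fold changes against control for each pair of stressors. Ammonia with the mixture (0.93) has the highest value, the 3 oil and dispersant exposures lie at 0.74 to 0.87, and 95% of simulated unchanged groups with shared controls lie between -0.14 and 0.82. The simulated controls were drawn from arrays of all groups and not from the control arrays alone.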

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

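The tests of shared control arrays and channel brightness for copper and salinity were chosen after the results were seen.

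Of 190 groups of arrays examined, 18 held 1 array far from the others, where chance gives about 1 in 20. Among array summaries these were the log2 median green signal of mixture replicate 3 (6.24), oil replicate 3 (4.91) and silver replicate 1 (5.86), the percentage of probes well above background in green on oil replicate 3 (41.7) and silver replicate 1 (83.1), and in red on oil replicate 3 (85.5). Among log2 ratios of named probes these were CUST_343_PI426266160 on cadmium replicate 5 (-1.28), CUST_3841_PI426266160 on ammonia replicate 4 (3.45), CUST_1840_PI426266160 on salinity replicate 5 (2.84), CUST_2673_PI426266160 on control replicate 6 (-0.30) and CUST_831_PI426266160 on control replicate 4 (-0.085). On dispersant replicate 5 these were CUST_2172_PI426266160 (2.62), CUST_2144_PI426266160 (-0.61) and CUST_14_PI426266160 (0.14). CUST_14_PI426266160 lay apart on oil replicate 5 also (-1.48), CUST_1677_PI426266160 on dispersed oil replicate 5 (9.65), CUST_1443_PI426266160 on silver replicate 1 (-1.11) and CUST_4633_PI426266160 on mixture replicate 4 (0.018).

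The exposed channel was brighter on the arrays of some groups than of others. If only the amount of labelled algal RNA differed, the spike-in signal would not follow it, yet the slope of the spike-in green signal on that of the probes over the 56 arrays was 0.763, with a lower 95% bound of 0.707. Labelling or scanning of the whole channel may therefore account for much of the difference. A biological part stays open, since the slope was 0.892 within groups and 0.686 over group means. The bound came from resampling arrays without regard to group, so it does not hold for the slope over group means.

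The copper and salinity responses resembled each other. Shared control arrays alone do not give this, as the covariance was 0.0905 and the upper limit of the central 95% of simulated unchanged groups was 0.0262. Slide was not the whole cause, as r was 0.64 with slide as a block (jackknife SE 0.0527). With the green signal as a covariate r was 0.57, but this fit cannot settle the part of brightness. Every copper array was brighter in green than every control array, so the fit extends a slope found within groups across that gap. Brightness of the exposed channel is therefore not excluded as a cause. A response common to these exposures is a hypothesis that may be followed up, found and tested on the same data.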

How the results depend on the processing

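The green signal as a covariate, scan day as a block and leaving out the dim arrays were chosen after seeing the data. Counts stayed within 1.5 times the reported ones in all comparisons with no filter, replicate number as a block (copper 1512), a trended robust eBayes and scan day as a block. Quantile normalization of the average signal leaves the log2 ratios as they are, so its counts equal the reported ones and test nothing. Same-numbered arrays of a stressor and the control correlated above 0.1 in 21 of 50 pairs (-0.63 to 0.72). Differently numbered arrays were not set beside them, so this does not settle whether the numbers pair the arrays. The cause was not tested for the changes below, except that the strict filter tests 1593 probes and so gives fewer calls. Depth limits the dim arrays, with 41.7% of probes well above background in green on the lowest.

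Without background correction 1000 probes were called with dispersed oil against control and 175 against dispersant. With the processed signals the counts were 986 for copper, 618 for silver, 1327 for dispersed oil, 14 for dispersed oil against oil, 390 for dispersed oil against dispersant and 1105 for silver against copper. With the deposited value table these were 974, 604, 1321, 14, 401 and 1106. Median centring gave 329 for cadmium, 2365 for silver, 315 for oil, 100 for dispersed oil, 4 for dispersed oil against oil, 542 for mixture against ammonia and 820 for silver against copper.

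The strict filter gave 662 for copper, 666 for cadmium, 460 for silver, 875 for simazine, 1218 for ammonia, 728 for salinity, 1217 for the mixture, 550 for oil and 565 for dispersant. It gave 3 for dispersed oil against oil, 138 for oil against dispersant, 529, 1194 and 1209 for the mixture against ammonia, cadmium and salinity, 623 for silver against copper, 889 for silver against cadmium, 807 for cadmium against copper and 609 departures from the sum. With it falls came to outnumber rises for copper (290 and 372), silver (182 and 278), simazine (337 and 538), salinity (319 and 409), silver against cadmium (393 and 496) and the mixture against salinity (590 and 619). Rises came to outnumber falls for dispersant (306 and 259), dispersed oil (188 and 175), the mixture against ammonia (291 and 238), cadmium against copper (431 and 376) and the departure from the sum (373 and 236).

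With slide as a block the counts were 15 for dispersed oil against oil and 7 against dispersant. A fit of only the groups compared gave 2177 for cadmium, 1961 for silver, 1763 for oil, 1884 for dispersant, 2 for dispersed oil against oil, 3 against dispersant, 142 for oil against dispersant and 460 for mixture against ammonia. Ratios tested against 0 gave 2197 for cadmium, 1604 for silver, 1985 for oil, 1953 for dispersant and 1142 for dispersed oil. The green covariate gave 18 for dispersed oil against oil, 38 against dispersant and 1215 for cadmium against copper. Without the 3 dim arrays the counts were 837 for dispersed oil and 21 against dispersant.

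Leaving out single arrays, the counts ran from 281 to 787 for dispersed oil, 6 to 12 against oil, 8 to 275 against dispersant and 109 to 285 for oil against dispersant. Those outside 1.5 times are named in the report. The correlation of salinity and mixture turned to -0.21 with median centring and was 0.074 with the strict filter. That of cadmium and mixture was 0.17 with the processed signals and with the deposited value table. With the green covariate those of copper and silver and of cadmium and silver turned to -0.0039 and 0.039. Of the values of named probes, 1735 under the alternatives fixed beforehand and 231 under those added kept direction and call, and 28 and 6 kept the direction but lost the call.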

Other observations

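The neighbour test with its threshold, the shuffled order, the probes named next and the tests of sequence records were chosen after seeing the data. Of 4485 probes, 168 were called with no stressor and 26 with all 10, of which 3 rose and 15 fell throughout. CUST_1582_PI426266160 rose by 0.24 to 1.69 on the log2 scale and CUST_435_PI426266160 by 0.26 to 0.86. CUST_2395_PI426266160 lay between -1.43 and -0.30 and CUST_4013_PI426266160 between -1.40 and -0.34. These comparisons share the control arrays. Of 230 tests of the 23 sequence records as groups of probes (camera, limma), 0 passed, with a smallest adjusted p of 0.999, and of 1 with an estimated correlation.

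Probes next to each other in the numbering of a sequence record followed each other over the 10 stressors more often than in a shuffled order. Of 4242 such pairs, 55 correlated above 0.95, against a mean of 34.0 and a highest count of 48 in 100 shuffles, so 0 shuffles gave as many. In CUST_2533_PI426266160 and CUST_2535_PI426266160 the log2 fold changes with ammonia were -5.62 and -6.47. Nearby spots do not account for it, since the median distance of the closest spots was 20 and the 5th to 95th percentiles of the median of random pairs were 17.0 to 24.0. Near-identical copies of a gene could not be examined, as the files hold no sequences, and shared regulation may be a hypothesis only.

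Other splits of the same arrays were drawn, 100 per comparison with the real one included. They ignore the slide. In the comparisons with control the real split gave the most calls and was the 1 split to reach its count: copper 1666 (highest other 1172), cadmium 1338 (909), silver 1018 (555), simazine 2010 (1570), ammonia 3290 (2664), salinity 1889 (1365), mixture 3149 (2821), oil 1086 (457), dispersant 1232 (757) and dispersed oil 508 (483). So it did for the mixture against ammonia at 1493 (1336), cadmium at 2991 (2242) and salinity at 3171 (2546), silver against copper at 1662 (862) and cadmium at 2133 (1631), and cadmium against copper at 2029 (1413). For these comparisons 1 of 100 is the smallest share such splits can give. Chance could be excluded at that share only, for each comparison taken alone and without correction for their number. The count for the mixture against ammonia is not firm. The median of its other splits was 49, a fit of these groups alone called 460 and median centring 542. On slides left out of the calls 74.5% to 81.9% of probes had the same sign, and the splits do not exclude the slide. For oil against dispersant the real split also gave the most calls, at 253 (136). There 46.3% of 380 probes called without slide 3 had the same sign on it, and leaving out single arrays gave 109 to 285, so the slide is not excluded and the count is not firm. For dispersed oil against dispersant 3 of the 100 splits gave as many as 78, the highest other giving 276. This share is small, but many comparisons were tested in this way without correction. Chance is therefore not excluded here, and these splits, like all of them, do not exclude the slide. The count was 7 with slide as a block, on slides left out of the calls 17 of 23 and 10 of 16 probes had the same sign, and leaving out single arrays gave 8 to 275, so the count of 78 is not firm. For dispersed oil against oil chance could not be excluded: 17 of the 100 splits gave as many as 7 probes, and the highest gave 386. In both comparisons a split that calls several times the real count points to a structure of the arrays, and which one was not tested. For the departure from the sum 5 of 100 gave as many as 1593 and the highest other 2282, so these splits do not exclude chance. They exchange arrays of groups that differ at up to 3290 probes, so they are no splits of unchanged arrays and do not show that chance gave the departure. The count was 1476 with slide as a block, and leaving out single arrays gave 1400 to 1774.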
